A study of Homo sapiens with 18 samples.

How the data were processed

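RNA-seq libraries were prepared from acini of MCF-10A.B2 cells, WT or JNKKO, treated with ethanol, B/B homodimerizer, or homodimerizer with TGF-β1, with 3 libraries in each of 6 groups. RNA was extracted with a miRNeasy kit with DNase treatment, selected with oligo(dT) beads, depleted of ribosomal RNA, primed with random hexamers and sequenced from both ends on a NovaSeq6000, per the labels' protocols. Poly(A) selection keeps polyadenylated transcripts, so other RNA is counted only in part. Reads were trimmed with cutadapt, quantified with RSEM and referred to hg38, per the submitters' processing notes. The aligner, the annotation, the versions and the use of strand are not given in the sources used here, so values of overlapping and antisense genes are uncertain. RSEM divides reads between near-identical genes by a model, so paralogs and pseudogenes are uncertain too.

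The authors deposited, for each gene, RSEM expected counts, which need not be whole, and transcripts per 1000000 (TPM), both per the file headers. A median of 9.35% of the values per library were not whole, and each deposited TPM column summed to 1000000. Each of the 42141 genes in the tables was matched by its transcript identifiers to GENCODE 29, the annotation used here for positions and gene types, which found 42125 genes (99.96%). Altered gene names, 127 in the deposited tables, were found, 51 turned into a currency amount or a name with a space and 76 by JNKKO standing in place of E3, and these were restored before any test. Of the 76, 42 restored names equalled the GENCODE 29 symbol. Names are printed as in the deposited tables, so some are older symbols, such as CYR61 for CCN1.

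Samples were grouped by title. One library, WT dimerizer with TGF-β1 replicate 3, has a genotype tag that contradicts its title, and every comparison that uses it was repeated without it. Library totals ran from 24243537 to 34499651 expected counts, which gives a gene at 5 CPM more than 100 counts in each library. The common biological coefficient of variation was 4.47%, and the lowest correlation between replicates of a group was 0.997. No replicates agreed within sampling noise, with a chi-square per gene between 2.28 and 12.1 over replicate pairs, so each library was counted once. The highest values, 9.50 and 12.1, both came from pairs with WT dimerizer with TGF-β1 replicate 1. Replicates 2 and 3 of that group were at 3.39.

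Expected counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust dispersion estimates) in R 4.3.3, with 1 mean per group and all 18 libraries in the same model. Library sizes were scaled with TMM factors, which lay between 0.962 and 1.04, and genes were filtered with the default rule of edgeR, which kept 16911. The Benjamini-Hochberg method was applied over all genes of a comparison, with a threshold of 0.05, and standard errors were taken as the log2 difference divided by the square root of F. The 11 comparisons were dimerizer against control, dimerizer with TGF-β1 against dimerizer and against control in each genotype, JNKKO against WT in each treatment, and the interactions of genotype with dimerizer and with TGF-β1. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Principal components used log2 CPM with a prior count of 2.

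Gene lists were tested with camera of limma 3.58.1 on log2 CPM, with the correlation between members estimated and adjustment over the 26 lists of a comparison. The lists were JNK pathway components, AP-1 family, ERK pathway feedback, ERBB receptors and ligands, TGF-β response, mesenchymal markers, epithelial junction and polarity, basal and myoepithelial markers, luminal markers, proteases and invasion, proliferation, apoptosis of lumen clearance, p53 targets and senescence, inflammatory cytokines and NF-κB targets, type I interferon response, hypoxia and glycolysis, cholesterol biosynthesis, unfolded protein response, squamous differentiation, YAP/TAZ targets, Notch pathway, axon guidance and cell migration signals, mitochondrially encoded genes, heat shock, fibroblast markers, and immune and endothelial markers. Counts of called members are given over all genes tested and, where different, adjusted over the list alone.

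The groups, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule took, per comparison of groups, the 8 largest rises and the 8 largest falls among genes that passed the test, reached 5 CPM on average in the higher group, did not overlap between the 3 and 3 libraries, and had a proper symbol that was not a pseudogene. It added from each list up to 4 called members with the smallest adjusted p, and MAPK8, MAPK9, MAPK10, ERBB2, NGFR, EGFR, JUN, FOS, CDH1, CDH2, VIM, FN1 and MKI67 throughout. For dimerizer with TGF-β1 against control only the list members and these genes were taken, and for each interaction the 4 largest positive and 4 largest negative values. Separation of 3 from 3 libraries happens by chance in 10% of cases. From the genes so named, those described are examples, and a few are not reported here. Where a group held 1 to 3 counts of a gene, the ratio is given with its exact 95% counting interval.

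The test was run first on simulated data made from each gene's mean over all 18 libraries and from their library sizes, with changes put in WT dimerizer. Of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold it recovered 47.8%, 74.0%, 89.6% and 93.9%, and it called 11 unchanged genes among the 16516 tested. Only 46 to 50 genes were changed at each fold. In the real comparisons 32.9% to 67.3% of the genes passed, so these rates need not hold there. The alternatives tried were median-of-ratios scaling, DESeq2 1.42.0, no filter and a stricter filter on low counts, only the compared groups in the fit, the replicate number as a block, each library left out in turn, and limma on log2(TPM + 1) and log2(TPM + 0.1). For lists they were camera with a preset correlation, fry and camera with the block, and for overlaps only genes changed at least 2-fold. The removal of mitochondrial genes before scaling, and the overlaps under each of these settings, were added after the data had been seen. The whole of both deposited tables was used, and isoforms were not analysed here.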

Results

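RNA was sequenced from acini of MCF-10A.B2, a human non-tumour mammary epithelial line that carries a chimeric HER2 whose kinase can be paired on demand by a small bivalent drug. The chimera joins an outer part of the nerve growth factor receptor NGFR to the HER2 kinase, so counts assigned to ERBB2 and NGFR may mix the cells' own genes with the transgene. Parental (WT) and JNK-knockout (JNKKO) cells grew in a basement membrane gel for 21 days. After the first 7 days, EGF gave way for 14 days to ethanol (control), to the B/B homodimerizer, or to the dimerizer with TGF-β1, a cytokine that drives epithelial cells toward mesenchymal features. The question was how expression in WT and JNKKO cells differs during transformation in 3D culture. The 6 groups held 3 libraries each, 18 in all, with totals of 24243537 to 34499651 expected counts. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

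Transcripts encoded by mitochondria took 15.2% ± 0.131 of the counts in WT control, 9.0% ± 0.128 in WT dimerizer and 9.19% ± 0.641 in WT dimerizer with TGF-β1 (SD, n = 3). In JNKKO cells the shares were 10.8% ± 0.125, 8.90% ± 0.152 and 5.38% ± 0.166. The lowest share in WT control, 15.1%, lay above the 10.9% that was the highest of the other 15 libraries. A property of the WT control cultures or their RNA therefore cannot be told apart from genotype or treatment in any comparison that holds them. JNKKO dimerizer with TGF-β1 stood apart too, at 5.24% to 5.56%. The lowest of the libraries outside that group was at 8.61%, in WT dimerizer with TGF-β1 replicate 3. The same limit holds for every comparison with JNKKO dimerizer with TGF-β1. The first principal component of the 16911 genes tested held 51.2% of the variance and the second held 19.04%. Expression below is given as counts per 1000000 (CPM), mean ± SD of n = 3 libraries, and differences as log2 values ± the standard error of the model.

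**Figure D1:**
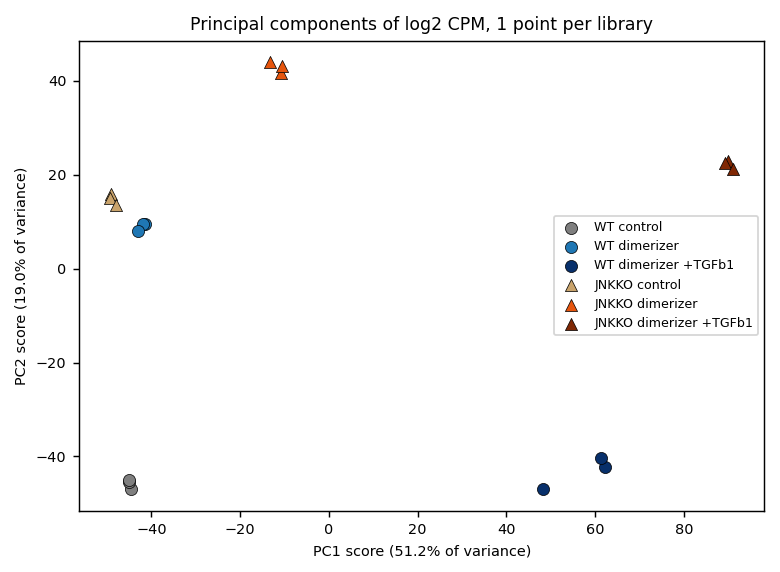
First (51.2% of the variance) and second (19.04%) principal components of log2 CPM, 1 point per library, coloured by the 6 groups of 3. The libraries with TGF-β1 lie between 48.4 and 91.2 on the first axis, and the other 12 libraries lie below 0.

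The knockout was examined first in the genes for the JNK kinases themselves. MAPK9 (JNK2; chromosome 5, 180233143 to 180292099, minus strand, hg38) stood at 63.0, 62.9 and 59.3 CPM in the WT control libraries, 57.1, 59.4 and 61.4 in WT dimerizer, and 64.7, 68.4 and 65.4 in WT dimerizer with TGF-β1. The JNKKO libraries held 45.4, 42.1 and 44.6 CPM in control, 44.6, 42.7 and 44.3 with dimerizer, and 51.0, 53.9 and 52.2 with TGF-β1. MAPK9 was thus lower in all 9 JNKKO libraries than in all 9 WT libraries, and the log2 differences between JNKKO and WT were -0.49 ± 0.04 in control, -0.44 ± 0.04 with dimerizer and -0.34 ± 0.04 with TGF-β1 (edgeR quasi-likelihood test, largest Benjamini-Hochberg adjusted p = 4.21e-09).

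MAPK8 (JNK1; chromosome 10, 48306639 to 48439360, plus strand) was at 25.3, 22.8 and 24.7 CPM in WT control, 28.6, 31.1 and 29.6 in WT dimerizer, and 31.6, 35.1 and 33.0 in WT with TGF-β1. The JNKKO libraries held 34.9, 33.5 and 32.0 CPM, 29.9, 29.3 and 28.9 CPM, and 26.7, 25.5 and 27.4 CPM in the same order of treatments. MAPK8 was therefore higher by 0.47 ± 0.06 in JNKKO control, lower in JNKKO with TGF-β1, at -0.32 ± 0.06, and at -0.02 ± 0.05 with dimerizer (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.811). On the deposited TPM the last MAPK8 difference passed the test, with a mean of 6.42 ± 0.098 in JNKKO against 9.18 ± 0.569 in WT (-0.45 on the log2(TPM + 1) scale, limma), and MAPK8 was at 0.20 in control and -0.61 with TGF-β1 on that scale. The MAPK9 differences there were -0.57 in control, -0.80 with dimerizer and -0.71 with TGF-β1.

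MAPK10 (JNK3; chromosome 4, 85990007 to 86594625, minus strand) had fewer counts: 10.51, 10.04 and 8.999 CPM in WT control, 4.85, 4.67 and 5.59 in WT dimerizer, and 4.23, 4.11 and 3.89 in WT with TGF-β1. In JNKKO cells it was at 6.30, 7.31 and 7.51 CPM, 7.47, 7.35 and 6.15 CPM, and 3.64, 4.03 and 3.81 CPM. The MAPK10 difference between JNKKO and WT was -0.49 ± 0.10 in control and 0.47 ± 0.11 with dimerizer, and -0.09 ± 0.12 with TGF-β1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.555). Exons that remain after an edit can still be transcribed, so a level near that of WT does not contradict a label. The sources used here do not give which of the 3 genes were edited or where.

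**Figure D2:**
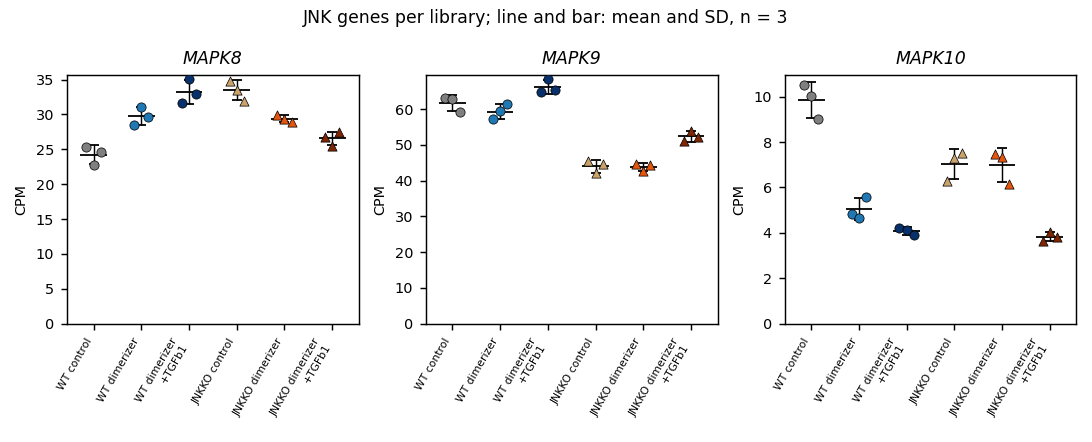
CPM of MAPK8, MAPK9 and MAPK10 in each of the 18 libraries (points) with the mean and SD of each group of 3. MAPK9 lies between 57.1 and 68.4 CPM in the WT libraries and between 42.1 and 53.9 CPM in the JNKKO libraries.

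PCSK1N also separated the genotypes in all 18 libraries. This gene, which encodes the proprotein convertase inhibitor proSAAS, stood between 9.08 and 17.7 CPM in the 9 WT libraries and at most at 0.0701 CPM in the JNKKO libraries, 4 of which held no count. The library titled WT dimerizer with TGF-β1 replicate 3, whose genotype tag reads JNK knockout, held 17.7 CPM of PCSK1N and 65.4 CPM of MAPK9. It was grouped by its title, and the 4 comparisons that use it were repeated without it. Their counts of called genes went from 11023 to 10487, from 10452 to 9926, from 8952 to 8434 and from 5570 to 5067. The transgene's partners were at 86.1 ± 4.85 CPM for ERBB2 and 240.7 ± 23.7 CPM for NGFR in WT control.

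To see what pairing of the HER2 chimera changes in WT acini, WT dimerizer was set against WT control. The lysosomal glycoprotein gene GPNMB rose by 3.37 ± 0.29, from 67.7 ± 4.57 to 701 ± 52.4 CPM. CLDN1, a tight junction claudin, rose by 2.91 ± 0.18, the basal keratin KRT15 by 2.65 ± 0.12, the growth factor FGF1 by 2.95 ± 0.18 and the lipid carrier APOE by 3.03 ± 0.17. The Wnt antagonist DKK1 fell by 5.64 ± 0.11 on the log2 scale, from 96.6 ± 1.32 to 1.93 ± 0.0826 CPM. The transcription factor ATOH8 fell, at -4.91 ± 0.11, the BMP inhibitor SMAD6 at -4.54 ± 0.20, the matrix protease MMP7 at -4.05 ± 0.15 and the homeobox factor DLX3 at -3.82 ± 0.25. Among these genes the largest adjusted p was 4.22e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg).

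Of the ERK pathway feedback list in WT dimerizer 17 rose and 2 fell of 22 measured members, among them SPRED1 at 1.49 ± 0.06 and the ETS factor ETV5 at 1.26 ± 0.08, while EPHA4 fell by 1.76 ± 0.11. That list, called ERK feedback genes below, holds DUSP, SPRY and SPRED genes but also others, such as ETV and EGR factors, CCND1 and MYC. Among ERBB receptors and ligands 9 rose and 2 fell of 15 (10 and 2 adjusted over the list alone): the ligand BTC rose by 1.68 ± 0.24 and the feedback protein LRIG1 by 0.91 ± 0.06, while EGFR fell by 0.49 ± 0.05. Genes of cholesterol synthesis 19 rose and 0 fell of 23, with SQLE at 0.84 ± 0.04, MSMO1 at 0.82 ± 0.05 and the sterol carrier STARD4 at 1.39 ± 0.05. Proliferation genes (17 rose and 0 fell of 30) included CDK1 at 0.70 ± 0.10 and TTK at 0.84 ± 0.13, and MKI67, the Ki-67 gene, was at 0.17 ± 0.14 without passing the test, which it passed without WT control replicate 2 (0.36) or with no filter (0.18). Epithelial junction and polarity genes (15 rose and 3 fell of 28) included CDH1, the E-cadherin gene, at 0.84 ± 0.06 and the splicing factor ESRP1 at 1.05 ± 0.05. For these 5 lists camera of limma gave adjusted p of 0.392, 0.392, 0.392, 0.792 and 0.616 with an estimated correlation. The other counts of list members, here and below, were the same when adjusted over the list alone unless a second count stands beside them.

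Of AP-1 family genes 3 rose and 10 fell of 18, with FOSL2 at -1.12 ± 0.05. YAP/TAZ targets 8 rose and 10 fell of 20, and CYR61 fell by 2.23 ± 0.08. All 13 mitochondrially encoded genes fell, MT-ND2 at -1.39 ± 0.04 and MT-CYB at -1.01 ± 0.03, beside the drop of their share of counts from 15.2% to 9.0%. Of squamous differentiation genes 5 rose and 7 fell of 25, and the suprabasal keratin KRT10 fell by 2.84 ± 0.17. Apoptosis genes of lumen clearance 13 rose and 5 fell of 20 (14 and 5 adjusted over the list alone), while the BH3-only gene HRK fell by 3.47 ± 0.09. For the 5 lists camera of limma gave adjusted p of 0.279, 0.616, 0.279, 0.988 and 0.473 with an estimated correlation.

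Genes of the interferon response 10 rose and 5 fell of 25, with OAS1 at 1.66 ± 0.08 and OAS2 at 1.89 ± 0.21, and inflammatory genes 11 rose and 2 fell of 26, with the calprotectin subunit S100A8 at 1.56 ± 0.12. JNK pathway components 7 rose and 9 fell of 21 (7 and 6 in the limma test on TPM, where the majority turns), with the phosphatase DUSP1 at -0.96 ± 0.07. Luminal markers 2 rose and 5 fell of 13 (4 and 2 on TPM), with WFDC2 at 2.38 ± 0.29. Basal markers 10 rose and 4 fell of 20, p53 targets 8 rose and 3 fell of 16, proteases 9 rose and 6 fell of 23 (10 and 6 adjusted over the list alone), hypoxia genes 9 rose and 4 fell of 25, the unfolded protein response 7 rose and 5 fell of 22 and axon guidance genes 13 rose and 2 fell of 25 (13 and 3 adjusted over the list alone). TGF-β response genes 12 rose and 9 fell of 27 and mesenchymal markers 7 rose and 10 fell of 23, with COL1A1 at -1.25 ± 0.05 and the neural cadherin gene CDH2 at 1.23 ± 0.16. Over these lists adjusted p ran from 0.392 to 0.988 with camera of limma and an estimated correlation. FN1, the fibronectin gene, fell by 1.55 ± 0.51, a call that ended without WT control replicate 1 (-1.19) or 2 (-1.41) or WT dimerizer replicate 3 (-1.46), with only these groups in the fit (-1.57), or on log2(TPM + 1) (-0.81).

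In all, 9451 genes passed the test in WT dimerizer against control, 5125 higher and 4326 lower, of which 1428 changed at least 2-fold. In limma on log2(TPM + 1) the split was 6250 higher and 2814 lower, with the median of all genes at 0.09 on the log2 scale. That median lay at most 0.23 from 0 in any comparison on the TPM scales, and the counts of higher and lower genes are to be read against it.

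The dimerizer was then set against control in JNKKO acini. INHBA, which encodes an activin subunit, rose by 4.41 ± 0.20, from 5.12 ± 1.01 to 108 ± 4.95 CPM. The ectonucleotidase NT5E rose by 3.47 ± 0.15, the urokinase gene PLAU by 2.01 ± 0.09, the laminin chain LAMA3 by 1.83 ± 0.05 and the integrin chain ITGA5 by 1.89 ± 0.11. The matrix protein gene SPARCL1 fell by 3.16 ± 0.26, the imprinted RNA H19 fell, at -2.53 ± 0.19 and the suprabasal keratin KRT1 at -2.36 ± 0.19. PAPPA2, a protease gene, held 710 counts with dimerizer and 1 in control, a ratio of 685 with a 95% counting interval of 123 to 27107. CDH1 stood at 81.5 ± 3.05 and 81.5 ± 3.52 CPM in these groups and did not pass the test. Among the called genes the largest adjusted p was 3.84e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg).

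Of proliferation genes in JNKKO dimerizer 0 rose and 27 fell of 30 (0 and 28 adjusted over the list alone), with MKI67 at -1.23 ± 0.14, MYBL2 at -1.44 ± 0.13 and the thymidylate synthase gene TYMS at -0.66 ± 0.06. Epithelial junction genes 2 rose and 14 fell of 28, with EPCAM at -1.04 ± 0.10. Squamous differentiation genes 1 rose and 15 fell of 25 (1 and 16 adjusted over the list alone), with KRT10 at -1.82 ± 0.17, and interferon response genes 3 rose and 12 fell of 25 (3 and 14 adjusted over the list alone). These lists had adjusted p of 0.299, 0.316, 0.332 and 0.287 by camera of limma with an estimated correlation.

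Of 5 further lists none passed camera of limma, with adjusted p of 0.316 for TGF-β response genes and 0.228 for each of the others with an estimated correlation. TGF-β response genes 16 rose and 5 fell of 27 (17 and 5 adjusted over the list alone), with SKIL at 1.27 ± 0.07 and PMEPA1 at 1.40 ± 0.07. ERK feedback genes 18 rose and 1 fell of 22, with the phosphatase DUSP5 at 1.45 ± 0.09. Of hypoxia and glycolysis genes 21 rose and 0 fell of 25, with PFKP at 0.85 ± 0.07 and the prolyl hydroxylase P4HA1 at 0.86 ± 0.06. Of the unfolded protein response 20 rose and 0 fell of 22, with the chaperone HSPA5 at 0.56 ± 0.04, XBP1 at 0.98 ± 0.11 and CHAC1, a glutathione-degrading enzyme, at 3.93 ± 0.29. Protease genes 12 rose and 2 fell of 23 (13 and 3 adjusted over the list alone), with the urokinase receptor PLAUR at 1.27 ± 0.08. Of ERBB receptors and ligands 5 rose and 5 fell of 15 (6 and 5 adjusted over the list alone), with AREG at 1.85 ± 0.11, TGFA at 1.13 ± 0.05, LRIG1 at -0.61 ± 0.05 and ERBB2 at -0.41 ± 0.05. Of apoptosis genes 8 rose and 6 fell of 20 (9 and 7 adjusted over the list alone), a majority that turned to 6 higher and 7 lower in limma on TPM, and the apoptosis inhibitor MCL1 was at 1.07 ± 0.04. For these lists adjusted p were 0.942 and 0.666 by camera of limma with an estimated correlation.

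In this comparison 6829 genes passed, 3803 higher and 3026 lower, a majority that turned to 2815 higher and 3219 lower in limma on log2(TPM + 1), and 946 changed at least 2-fold. WT and JNKKO cells shared 1976 genes that rose with dimerizer, beside 1152.5 for independent lists, and 1360 that fell, beside 774. A further 1391 went in opposite directions, beside 1890 for independent lists. This deficit depended on the genes taken. Among genes changed at least 2-fold 59 were opposite, beside 39.4, while 146 rose and 128 fell in both, beside 24.8 and 15.7. With no filter 1387 were opposite, beside 1146, while 1963 rose and 1244 fell in both, beside 721 and 455. There the opposite count hardly moved. The value for independent lists fell as the genes tested grew from 16911 to 27495, so this setting does not show a change in the opposite genes. Across the 16911 genes, which are not independent replicates, the log2 values of WT and JNKKO had a Pearson r of 0.240 and a Spearman rho of 0.224.

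**Figure D3:**
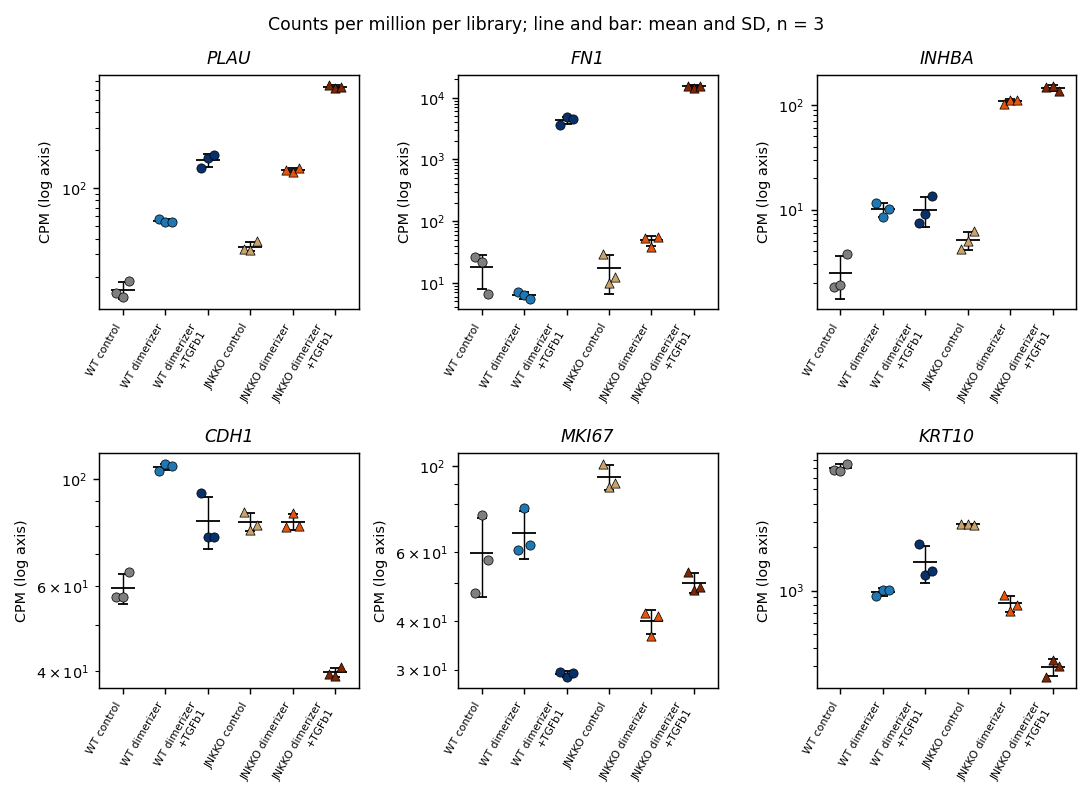
CPM on a log axis of PLAU, FN1, INHBA, CDH1, MKI67 and KRT10 in each of the 18 libraries (points), with the mean and SD of each group of 3. INHBA is at 5.12 ± 1.01 CPM in JNKKO control and 108 ± 4.95 CPM in JNKKO dimerizer.

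To see what TGF-β1 adds to the active chimera, WT dimerizer with TGF-β1 was set against WT dimerizer. POSTN (periostin) rose by 9.66 ± 0.39, FN1 by 9.43 ± 0.48, from 6.33 ± 0.756 to 4345 ± 622 CPM, the enamel-associated matrix gene AMTN by 9.27 ± 0.21 and the crosslinking enzyme TGM2 by 8.28 ± 0.24. The proteases FAP and MMP2 rose by 7.08 ± 0.10 and 5.86 ± 0.13 and the scaffold NEDD9 by 5.07 ± 0.10. KRT15 fell, at -5.85 ± 0.14, as did the desmosomal cadherin DSG1 at -5.75 ± 0.52, the calprotectin subunit S100A9 at -4.57 ± 0.15 and EPCAM at -2.03 ± 0.11. ALDH3B2, an aldehyde dehydrogenase, held 1 count with TGF-β1 and 547 with dimerizer alone, a ratio of 523 (95% counting interval 93.5 to 20706). Among these genes the largest adjusted p was 2.76e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg).

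Of the TGF-β response genes 25 rose and 0 fell of 27, with PMEPA1 at 4.93 ± 0.07 and SKIL at 2.52 ± 0.06. Mesenchymal markers 19 rose and 2 fell of 23, with CDH2 at 2.69 ± 0.10, COL1A1 at 3.01 ± 0.05 and the transcription factor SNAI2 at 1.60 ± 0.05. Proteases 17 rose and 3 fell of 23 and YAP/TAZ targets 16 rose and 3 fell of 20, with CYR61 at 1.99 ± 0.08. All 4 lists moved relative to other genes, with a camera adjusted p of 0.0268 each in limma with an estimated correlation. Epithelial junction genes 3 rose and 21 fell of 28, proliferation genes 0 rose and 29 fell of 30, with MKI67 at -1.20 ± 0.15, and squamous genes 2 rose and 22 fell of 25. Camera of limma gave adjusted p of 0.287, 0.359 and 0.341 for these lists with an estimated correlation.

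JUN, the AP-1 subunit that JNK phosphorylates, rose by 1.99 ± 0.07, from 81.9 ± 2.39 to 324 ± 24.9 CPM, among AP-1 genes of which 11 rose and 6 fell of 18. JNK pathway components 12 rose and 5 fell of 21, with the phosphatase DUSP10 at 1.62 ± 0.05. CDH1 fell by 0.37 ± 0.06, and the ESRP splicing factors ESRP1 and ESRP2 fell, at -0.81 ± 0.05 and -0.99 ± 0.06. Of the unfolded protein response 16 rose and 4 fell of 22, with the chaperone CALR at 0.75 ± 0.04. Camera of limma gave adjusted p of 0.125, 0.325 and 0.443 with an estimated correlation. In total 11023 genes passed, 5643 higher and 5380 lower (7150 and 3664 in limma on log2(TPM + 1)), with 2675 changed at least 2-fold.

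The effect of TGF-β1 in JNKKO acini was tested against JNKKO dimerizer. POSTN rose by 10.64 ± 0.34, FN1 by 8.28 ± 0.43, from 49.2 ± 9.09 to 15279 ± 685 CPM, the adhesion molecule CADM3 by 8.28 ± 0.36 and the elastic fibre protein FBLN5 by 7.80 ± 0.18. MMP2 rose by 6.11 ± 0.13, FAP by 7.11 ± 0.11, the follistatin relative FSTL1 by 4.74 ± 0.12 and the matrix glycoprotein SPARC by 3.69 ± 0.10. The 5-lipoxygenase activator ALOX5AP held 700 counts with TGF-β1 and 3 without, a ratio of 232 (95% counting interval 79.2 to 1129). CHI3L1, a secreted glycoprotein, fell by 4.90 ± 0.17, KRT15 fell, at -4.01 ± 0.13, KRT1 at -4.09 ± 0.35 and the phospholipase PLA2G4F at -6.84 ± 0.28. Among these genes the largest adjusted p was 2.45e-07 (edgeR quasi-likelihood test, Benjamini-Hochberg).

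In JNKKO cells CDH1 fell by 1.03 ± 0.07, from 81.5 ± 3.05 to 39.8 ± 0.896 CPM, ESRP1 and ESRP2 fell, at -1.25 ± 0.05 and -1.89 ± 0.07, and CDH2 rose by 3.05 ± 0.09. TGF-β response genes 26 rose and 0 fell of 27, mesenchymal markers 20 rose and 0 fell of 23 and proteases 17 rose and 2 fell of 23, and camera of limma gave adjusted p of 0.0216, 0.0197 and 0.0225 with an estimated correlation. ERBB receptors and ligands 1 rose and 11 fell of 15 (camera adjusted p = 0.0340 in limma with an estimated correlation): NRG2 fell, at -2.45 ± 0.22, LRIG1 at -1.90 ± 0.07, EREG at -1.51 ± 0.16 and EPGN at -0.83 ± 0.09. Epithelial junction genes 2 rose and 23 fell of 28. Of proliferation genes 13 rose and 3 fell of 30, with MYBL2 at 0.87 ± 0.14, and MKI67 was at 0.33 ± 0.15 without passing the test, which it passed with no filter (0.33), with only the groups compared (0.33), under DESeq2 (0.34), and on log2(TPM + 1) (0.51) and log2(TPM + 0.1) (0.60). For these 2 lists camera of limma gave adjusted p of 0.0698 and 0.795 with an estimated correlation.

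JUN rose by 2.06 ± 0.07 in JNKKO cells, MYC fell by 0.98 ± 0.04 and the BH3-only gene BMF rose by 2.73 ± 0.16. All 13 mitochondrially encoded genes fell, MT-ND1 at -1.38 ± 0.05 and MT-CO1 at -0.74 ± 0.04, beside the drop of their share from 8.90% to 5.38% of the counts, and YAP/TAZ targets 13 rose and 6 fell of 20 (camera adjusted p of 0.230 and 0.148 in limma with an estimated correlation). Here 10271 genes passed, 5154 higher and 5117 lower, against 8046 and 2631 in limma on log2(TPM + 1), and 2413 changed at least 2-fold. WT and JNKKO shared 3974 genes that rose with TGF-β1, beside 1720 for independent lists, and 3719 that fell, beside 1628. Another 548 went in opposite directions, beside 3347 for independent lists, and the log2 values correlated across genes with a Pearson r of 0.744 and a Spearman rho of 0.707.

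Dimerizer with TGF-β1 was also set against control acini, first in WT cells. TGF-β response genes 24 rose and 1 fell of 27, mesenchymal markers 18 rose and 3 fell of 23 (18 and 4 adjusted over the list alone), with FN1 at 7.87 ± 0.43, and proteases 16 rose and 3 fell of 23, with MMP2 at 6.54 ± 0.14. Each of these lists had a camera adjusted p of 0.0457 in limma with an estimated correlation, which did not pass without WT control replicate 1 (0.0739) or 2 (0.0744) or WT dimerizer with TGF-β1 replicate 2 (0.0535). Axon guidance genes 18 rose and 3 fell of 25, with the ephrin receptor EPHB2 at 2.84 ± 0.13, and squamous genes 1 rose and 20 fell of 25, with the transglutaminase TGM1 at -2.65 ± 0.08. The adjusted p were 0.0892 and 0.311 by camera of limma with an estimated correlation. Epithelial junction genes 6 rose and 13 fell of 28, a majority that turned to 13 higher and 7 lower on log2(TPM + 1), and CDH1 rose by 0.46 ± 0.06. That list had an adjusted p of 0.504 by camera of limma with an estimated correlation. The largest adjusted p among these genes was 2.29e-06 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 10452 genes passed, 5300 higher and 5152 lower (8346 and 2381 on log2(TPM + 1)), with 2482 at least 2-fold.

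In JNKKO cells the same pair of treatments gave TGF-β response genes of which 26 rose and 1 fell of 27, with PMEPA1 at 5.96 ± 0.07, mesenchymal markers of which 20 rose and 1 fell of 23, with CDH2 at 3.68 ± 0.10, and proteases of which 16 rose and 3 fell of 23, with FAP at 8.13 ± 0.13. Each had an adjusted p of 0.0266 by camera of limma with an estimated correlation. Epithelial junction genes 1 rose and 23 fell of 28, with EPCAM at -2.51 ± 0.11 and CDH1 at -1.03 ± 0.07, proliferation genes 1 rose and 24 fell of 30, with MKI67 at -0.90 ± 0.14, and the unfolded protein response 20 rose and 0 fell of 22, with EDEM1, a factor of protein degradation at the endoplasmic reticulum, at 1.03 ± 0.03. For these lists camera of limma gave adjusted p of 0.0915, 0.585 and 0.177 with an estimated correlation. The largest adjusted p among these genes was 7.02e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and 11379 genes passed, 5723 higher and 5656 lower (7751 and 3625 on log2(TPM + 1)), with 3463 at least 2-fold.

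The genotypes were next compared within each treatment, first in control acini. In JNKKO control the folate enzyme ALDH1L1 was higher than in WT control by 6.05 ± 0.21, SPARCL1 by 5.11 ± 0.32, H19 by 4.14 ± 0.22, the mucin MUC16 by 3.29 ± 0.25 and KRT1 by 2.88 ± 0.20. DKK1 was lower, at -3.61 ± 0.09, from 96.6 ± 1.32 CPM in WT to 7.90 ± 0.259 in JNKKO, as were the interleukin receptor IL1RL1 at -3.53 ± 0.12 and the nuclear protein SAMD11 at -3.69 ± 0.24. PCSK1N (1 count in JNKKO against 1024) was lower by a ratio of 919, with a 95% counting interval of 165 to 36342. Such intervals, here and above, cover counting error only. Among the called genes named here the largest adjusted p was 4.63e-08 (edgeR quasi-likelihood test, Benjamini-Hochberg).

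No list passed camera of limma with an estimated correlation between genotypes or in either interaction, although 9 to 13 of 26 did with a preset correlation, so the counts below describe called members. Of ERK feedback genes in JNKKO control 19 were higher and 2 lower of 22, with SPRED1 at 1.33 ± 0.06 and ETV5 at 1.15 ± 0.08, and the ERBB ligands AREG and NRG2 were at 1.30 ± 0.12 and 1.84 ± 0.17. Of proliferation genes 26 were higher and 0 lower of 30, with the replication helicase gene MCM2 at 0.62 ± 0.06. Epithelial junction genes (17 were higher and 3 lower of 28) included CDH1 at 0.46 ± 0.06, inflammatory genes (14 were higher and 2 lower of 26) S100A9 at 1.81 ± 0.12, Notch genes (9 were higher and 1 lower of 16) the ligand DLL1 at 3.44 ± 0.24, and squamous genes (16 were higher and 2 lower of 25) KRT1. AP-1 genes (2 were higher and 9 lower of 18) included JUN at -0.60 ± 0.07 and FOSL2 at -0.76 ± 0.05, and all 13 mitochondrial genes were lower, beside shares of 10.8% and 15.2% of the counts. JNK pathway components 7 were higher and 9 lower of 21. Camera of limma gave adjusted p from 0.158 to 0.641 over these lists with an estimated correlation. In control 8335 genes differed between genotypes, 4359 higher in JNKKO and 3976 lower, with 1292 at least 2-fold.

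With dimerizer, the adenylate cyclase ADCY1 was higher in JNKKO by 6.43 ± 0.35, the dynein heavy chain DNAH11 by 5.61 ± 0.29, the receptor TEK by 4.35 ± 0.18 and the retinoic acid enzyme ALDH1A2 by 4.30 ± 0.32. FN1 was higher by 2.96 ± 0.46, NT5E by 2.77 ± 0.14 and ITGA5 by 1.96 ± 0.11, and AREG was at 104 ± 2.99 CPM in WT and 398 ± 9.10 in JNKKO. DENND2D, a Rab activator, was lower, at -5.45 ± 0.24, as was the chemokine CXCL14, at -2.68 ± 0.19. PCSK1N held 3 counts against 1210, a ratio of 346 (118 to 1680.5, 95% counting interval). Among the called genes the largest adjusted p was 1.89e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg).

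Of hypoxia genes in JNKKO dimerizer 23 were higher and 0 lower of 25, with P4HA1 at 1.04 ± 0.06. ERK feedback genes (20 were higher and 1 lower of 22 (21 and 1 adjusted over the list alone)) included DUSP5 at 1.80 ± 0.09, and the unfolded protein response (18 were higher and 0 lower of 22 (19 and 0 adjusted over the list alone)) XBP1 at 0.79 ± 0.10. Of TGF-β response genes 17 were higher and 5 lower of 27. Proteases (10 were higher and 3 lower of 23 (13 and 3 adjusted over the list alone)) included PLAU at 1.35 ± 0.09, and mesenchymal markers (11 were higher and 2 lower of 23 (12 and 3 adjusted over the list alone)) VIM at 0.97 ± 0.05. Of proliferation genes 0 were higher and 23 lower of 30, with MKI67 at -0.76 ± 0.14, and CDH1 was lower, at -0.38 ± 0.06. Over these lists adjusted p ran from 0.124 to 0.509 with camera of limma and an estimated correlation. In total 6775 genes differed, 3654 higher and 3121 lower, with 910 at least 2-fold, and on log2(TPM + 1) the split turned to 1773 higher and 5425 lower (limma). JUN was higher by 0.21 ± 0.07, a call that ended without WT dimerizer replicate 3 (0.19) or JNKKO dimerizer replicate 1 (0.19) or 3 (0.15), or on log2(TPM + 1) (0.07). JNKKO and WT differed in the same direction in control and dimerizer at 1471 higher genes (942 for independent lists) and 994 lower genes (734), and in opposite directions at 1760 (1664).

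With TGF-β1, the hypoxia-induced carbonic anhydrase CA9 was higher in JNKKO by 5.12 ± 0.50, INHBA by 3.87 ± 0.17, the matrix protein dermatopontin (DPT) by 7.00 ± 0.39 and the epidermal caspase CASP14 by 4.85 ± 0.41. AREG was higher by 2.71 ± 0.11, the phosphatase DUSP4 by 2.20 ± 0.08, SPARC by 2.44 ± 0.08 and FN1 by 1.81 ± 0.31. CYP1B1, a cytochrome P450, was lower, at -2.92 ± 0.13, as were HRK at -2.25 ± 0.12, the receptor ERBB3 at -1.67 ± 0.10 and CDH1 at -1.04 ± 0.07, from 81.7 ± 10.1 CPM in WT to 39.8 ± 0.896 in JNKKO. PCSK1N held 2 counts against 1569, a ratio of 707 (195 to 5840.4, 95% counting interval). Among the called genes the largest adjusted p was 2.96e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg).

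Of proliferation genes in JNKKO with TGF-β1 26 were higher and 0 lower of 30, with MKI67 at 0.78 ± 0.15 and CDK1 at 1.13 ± 0.11. Hypoxia genes (23 were higher and 1 lower of 25) included PDK1 at 1.20 ± 0.06, and mesenchymal markers (15 were higher and 4 lower of 23) the transcription factor ZEB1 at 1.48 ± 0.08. Of ERK feedback genes 16 were higher and 3 lower of 22, and of squamous genes 15 were higher and 1 lower of 25. Epithelial junction genes (5 were higher and 18 lower of 28) included the desmosomal plaque gene DSP at -1.01 ± 0.04, and AP-1 genes (4 were higher and 10 lower of 18) ATF3 at -2.04 ± 0.21. Of YAP/TAZ targets 6 were higher and 14 lower of 20, and of JNK pathway components 5 were higher and 10 lower of 21 (5 and 11 adjusted over the list alone). All 13 mitochondrial genes were lower, beside shares of 5.38% and 9.19% of the counts. Camera of limma gave adjusted p from 0.231 to 0.290 over these lists with an estimated correlation. In total 8952 genes differed, 4485 higher and 4467 lower, which turned to 3486 higher and 5004 lower in limma on log2(TPM + 1), with 1608 at least 2-fold. Between control and TGF-β1 the genotype difference had the same direction at 2197 higher genes (1156 for independent lists) and 2052 lower genes (1050.3), and the opposite at 1232 (2206).

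Whether the dimerizer acted differently in the 2 genotypes was tested as an interaction. It holds the WT control libraries, so a property of those cultures cannot be told apart from a difference in response. The dimerizer response was higher in JNKKO than in WT for the aldehyde oxidase AOX1 by 5.76 ± 0.20 and for the nuclear protein SAMD11 by 4.68 ± 0.58, and lower for SPARCL1, at -4.53 ± 0.50, FGF1, at -4.47 ± 0.24, and CXCL14, at -3.77 ± 0.27 (largest adjusted p = 1.71e-07, edgeR quasi-likelihood test, Benjamini-Hochberg). Called members with higher and lower interaction values were counted per list. Of proliferation genes 0 were higher and 30 lower of 30, of epithelial junction genes 2 were higher and 18 lower of 28 (3 and 18 adjusted over the list alone), of mitochondrial genes 13 were higher and 0 lower of 13, of mesenchymal markers 12 were higher and 3 lower of 23, of AP-1 genes 9 were higher and 2 lower of 18 (9 and 3 adjusted over the list alone) and of the unfolded protein response 12 were higher and 0 lower of 22 (15 and 0 adjusted over the list alone). Over these lists adjusted p ran from 0.278 to 0.285 with camera of limma and an estimated correlation. The interaction passed for 7200 genes, 3611 higher and 3589 lower (2078 and 4886 on log2(TPM + 1)), with 1547 at least 2-fold.

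For TGF-β1 the response was higher in JNKKO for the epidermal genes CASP14 by 5.39 ± 0.65 and A2ML1 by 4.99 ± 0.89, and lower for the prolyl hydroxylase P4HA3, at -2.89 ± 0.49, and ALDH1A2, at -2.81 ± 0.61 (largest adjusted p = 7.70e-04, edgeR quasi-likelihood test, Benjamini-Hochberg). By interaction value, of proliferation genes 28 were higher and 0 lower of 30, of squamous genes 13 were higher and 1 lower of 25 (15 and 1 adjusted over the list alone) and of TGF-β response genes 3 were higher and 15 lower of 27 (3 and 18 adjusted over the list alone). These values start from dimerizer, where levels already differed. Against control, dimerizer alone had raised 16 and lowered 5 TGF-β response genes in JNKKO (12 and 9 in WT). For proliferation genes it was 0 and 27 (17 and 0 in WT). The interaction cannot tell a changed response from a changed start. Nor can it tell either from a property of the JNKKO cultures with TGF-β1, whose mitochondrial share stood apart from all other groups. Of basal markers 4 were higher and 12 lower of 20 (4 and 13 adjusted over the list alone), of YAP/TAZ targets 2 were higher and 11 lower of 20 (3 and 13 adjusted over the list alone), of AP-1 genes 2 were higher and 9 lower of 18 (2 and 10 adjusted over the list alone) and of mitochondrial genes 0 were higher and 13 lower of 13. Camera of limma gave adjusted p from 0.110 to 0.379 over these 7 lists with an estimated correlation. This interaction passed for 5570 genes, 2391 higher and 3179 lower (3332 and 1958 on log2(TPM + 1)), with 940 at least 2-fold.

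**Figure D4:**
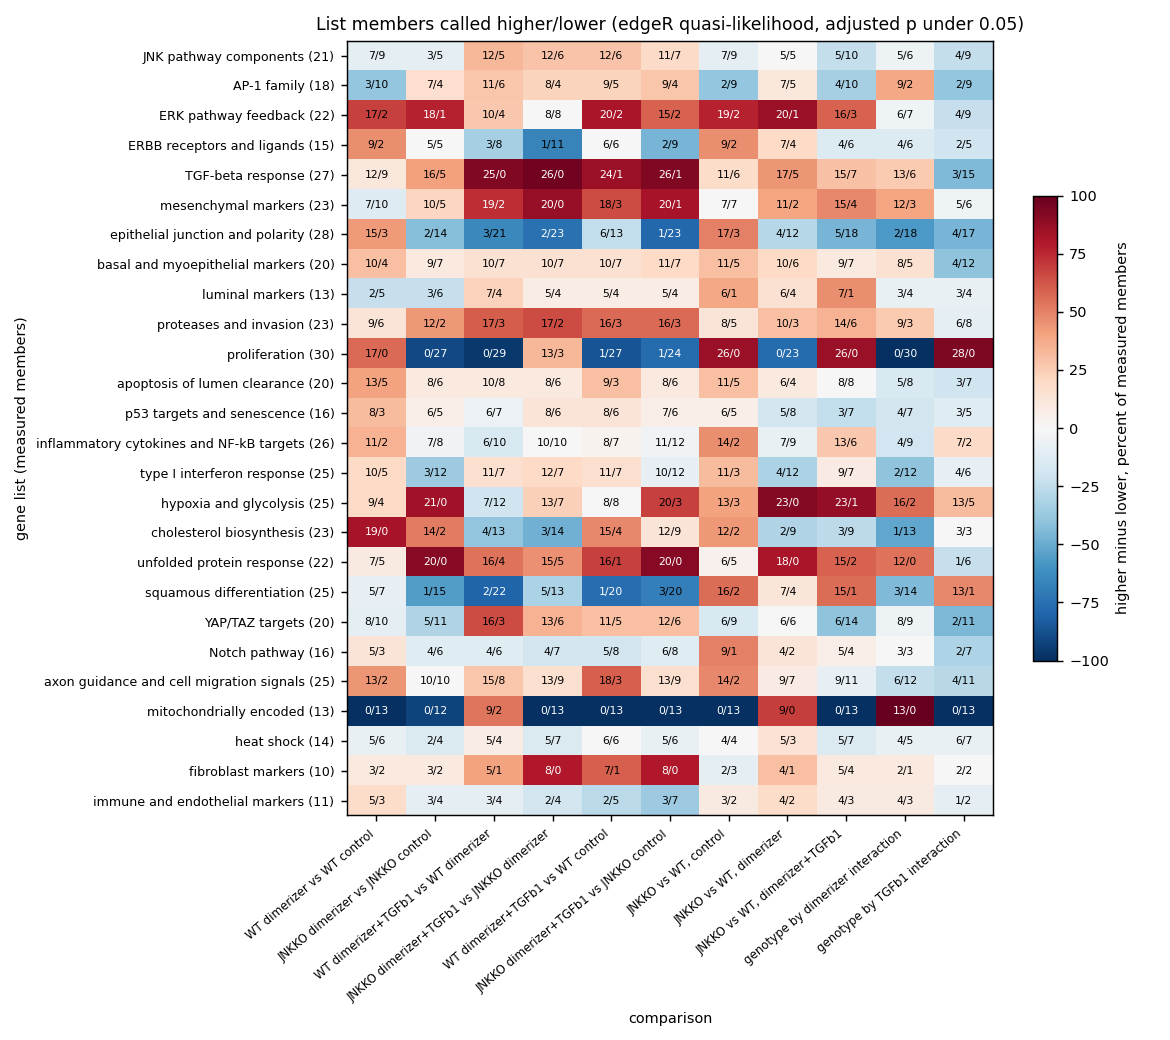
Share of each of the 26 gene lists' measured members called higher minus share called lower, in the 11 comparisons, with the counts of higher and lower members in each cell. Of the TGF-β response genes 25 rose and 0 fell with TGF-β1 in WT and 26 rose and 0 fell in JNKKO, while in WT dimerizer the majority of JNK pathway (7 and 9, or 7 and 6 on log2(TPM + 1)), luminal (2 and 5, or 4 and 2) and heat shock genes (5 and 6, or 6 and 4) turns in limma on TPM. It turns in other comparisons too. Examples are cholesterol genes with TGF-β1 against dimerizer in JNKKO (3 and 14, or 8 and 7) and mesenchymal markers in the TGF-β1 interaction (5 and 6, or 10 and 4).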

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

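The tests of a mixture of cultures, of a property of the WT control cultures and of a wrong title, and the covariance without a common control library, were chosen only after the results had been seen. The bounds of the other tests were written down before those tests were run.

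The difference between genotypes in their response to dimerizer, tested as an interaction, passed for 7200 genes. A property of the WT control cultures, which enter this interaction, cannot be told apart from such a difference. Its largest positive values were 5.76 ± 0.20 for AOX1, 4.68 ± 0.58 for SAMD11, 3.98 ± 0.29 for ITPKA and 3.92 ± 0.64 for C10orf10, and its largest negative values were -4.53 ± 0.50 for SPARCL1, -4.47 ± 0.24 for FGF1, -3.77 ± 0.27 for CXCL14 and -3.73 ± 0.19 for BBOX1. AOX1 rose from 2.90 ± 0.288 to 21.6 ± 3.92 CPM in JNKKO and stood at 12.02 ± 0.548 CPM in control and 1.64 ± 0.0907 CPM with dimerizer in WT (n = 3).

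For TGF-β1 the interaction passed for 5570 genes, with 5.39 ± 0.65 for CASP14, 4.99 ± 0.89 for A2ML1, 4.94 ± 0.74 for ALDH3B2 and 4.892 ± 1.246 for DPT, and -3.39 ± 1.31 for KCNJ6, -2.89 ± 0.49 for P4HA3 and -2.81 ± 0.61 for ALDH1A2. ALDH3B2 held 59 counts with TGF-β1 and 721 without in JNKKO, and 1 and 547 in WT, and KCNJ6 held 555 and 14 in JNKKO and 159 and 0 in WT, so these fitted values depend on the prior count. The call of ALDH3B2 ended on log2(TPM + 1) (0.14). The call of DPT ended without WT dimerizer replicate 1 (3.63). That of KCNJ6 ended without any 1 of WT dimerizer replicates 1 (-3.39), 2 (-3.38) and 3 (-3.38), WT dimerizer with TGF-β1 replicate 2 (-3.05), JNKKO dimerizer replicates 1 (-3.24) and 2 (-3.06), and JNKKO dimerizer with TGF-β1 replicates 1 (-3.35), 2 (-3.40) and 3 (-3.45), and also under DESeq2 (-2.93) and with only the groups compared (-3.41).

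For each interaction 100 of the 200 possible splits of the genotype labels within the treatments were drawn, the real one included. For dimerizer 1 of 100 splits, the real one, gave as many genes, 7200 against 4393 in the highest other, and for TGF-β1 2 of 100 did, 5570 in the real split against 8964 in the highest other, which exchanged the genotypes in 1 treatment. Splits that mixed the genotypes in both treatments called 0 genes, because the difference between genotypes then enters the spread within groups, so these splits do not decide about chance for the interactions. For the 9 comparisons of 3 against 3 libraries, where the real split alone gave as many genes (1 of 10), the 10 splits are too few for a share under 0.05. Every other split there also mixed both groups, so their difference entered the spread within groups, and these splits do not decide about chance either. The real counts of the 9 comparisons and the highest of the other splits were, in the order of the report, 9451 and 0, 6829 and 1, 11023 and 0, 10271 and 0, 10452 and 0, 11379 and 0, 8335 and 2, 6775 and 0, and 8952 and 0 by edgeR.

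In JNKKO cells 16 of 27 TGF-β response genes rose and 5 fell with dimerizer and no added TGF-β1, and the list did not pass camera of limma (adjusted p = 0.316 with an estimated correlation). RNA from the TGF-β1 cultures in these libraries would add the same share of every transcript. INHBA, however, reached 73.3% and FN1 0.209% of the way to the TGF-β1 level. The 20 most abundant genes that TGF-β1 raised at least 16-fold reached a median of 3.37%, against 7.08% for the 16 list members that rose. Those 16 were picked for their rise with dimerizer and the 20 were not, so the gap between the medians does not decide about a mixture. The first bound for the median of the 20 did not decide. A bound on how many of the 20 lay far below the median of those 16 (7) was added afterwards. It went against a mixture but rests on the same choice of genes. Within the 20 themselves the share ran from -0.0231% for POSTN to 73.3% for INHBA, which a mixture alone would not give. Scaling is argued against by the 14 of 16 genes that stayed called under DESeq2, on log2(TPM + 1) and without mitochondrial genes, and the 15 under median-of-ratios scaling. A response of JNKKO cells to dimerizer and a property of these cultures or cell populations both stay open and were not tested.

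JNKKO control and WT dimerizer differed from WT control in the same direction at 3508 higher and 3118 lower genes (1321 and 1017 for independent lists) and in opposite directions at 111. The 2 comparisons share the WT control libraries, and the covariance of their log2 differences across genes was 0.269, beside a mean of 0.0262 in 20 simulations of unchanged groups against those controls, a difference of 0.243, with a Pearson r of 0.759 beside 0.500. The ratio to the highest simulated covariance, 8.45, fell short of the 10-fold bound set for it, and the covariance was then computed with no control library in common, which left 0.236 to 0.245 over 6 ways of parting them and argues against chance values of the shared libraries. A property of the WT control cultures or their RNA cannot be told apart from genotype and treatment, since all 3 belong to 1 group: their lowest mitochondrial share was 15.1%, above the 10.9% that was the highest of the other 15 libraries. That JNKKO cells in control resemble WT cells with an active HER2 chimera may therefore be a trait of the genotype or of the WT control group, and remains a hypothesis.

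At 1089 genes JNKKO was called higher than WT in all 3 treatments (249.8 for independent lists) and at 794 lower (194), and 180 of these differed at least 2-fold throughout, 123 higher and 57 lower. Gained or lost chromosome segments would put such genes side by side. None of 15743 windows of 50 neighbouring genes reached the bound of 0.4 in all treatments, so 0% of the 180 could lie in such windows. Shorter segments, or changes in only part of the cells, could stay under that bound, so the windows do not decide about them. The window with the largest shift in all 3, on chromosome 5 (140806929 to 141512979), was at 0.637 in control, 0.295 with dimerizer and 0.230 with TGF-β1. A window on chromosome 15 (20642799 to 33864825) was at -0.250, -0.273 and -0.219 in the same order. A wrong title of WT dimerizer with TGF-β1 replicate 3 is argued against by 92.6% of 243 genes, 225 in number, for which it lay nearer its titled group than JNKKO. Loss of JNK and any other difference between the cell populations coincide in these samples, so the design leaves open which of them the differences may come from.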

How the results depend on the processing

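The removal of mitochondrial genes, and the overlaps under settings other than the 2-fold limit, are tests chosen only after the results had been seen. Without 1 library the 252 counts of called, 2-fold and shared genes stayed within 1.5 times their value, as did all 30 under each of DESeq2, median-of-ratios scaling, either filter, only the compared groups and no mitochondrial genes. Of 1133 results for single genes, 1126 kept direction and call under DESeq2, 1132 under median-of-ratios scaling, 1124 with no filter, 1124 with only the compared groups, 1104 on log2(TPM + 1) and 1107 on log2(TPM + 0.1), and so did 1128 of 1131 under the stricter filter and 1095 of 1097 without mitochondrial genes. With 1 library left out 6833 of 6888 did, 50 lost and 5 gained the call. Replicate numbers do not pair the samples (correlation of same-number deviations from -0.0624 to 0.0767 over 45 pairs, and 8 of 18 libraries nearest their own number); with the number as a block all 30 counts stayed within 1.5 times, 1132 of 1133 gene results and all 14 list calls were kept.

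On log2(TPM + 1) the genes changed at least 2-fold were 447, 292, 1277, 1159, 1338 and 1906 for the treatments in the order of the report, 354, 225 and 582 between genotypes, and 659 and 401 for the interactions, since the added 1 shrinks the differences of low genes. Limited to 2-fold genes the overlaps, higher and lower, were 146 and 128 for dimerizer, 888 and 655 for TGF-β1, 162 and 81 for the genotypes in control and dimerizer, and 305 and 158 in control and TGF-β1, since fewer genes enter. For independent lists these would be 24.8 and 15.7, 103.1 and 88.0, 26.3 and 10.2, and 44.8 and 19.1. In the same order, genes in opposite directions at that limit were 59 (39.4 for independent lists), 16 (190.6), 70 (33.0) and 59 (59.0). On log2(TPM + 1) and log2(TPM + 0.1) the genes lowered by TGF-β1 in both genotypes were 1936 and 1959, and those of the genotypes in control and dimerizer 789 and 808 higher and 1497 and 1502 lower. The same settings turned the direction, with TGF-β1 against dimerizer in JNKKO, of MAPK8 (0.10 and 0.12), ERBB2 (0.10 and 0.11) and VIM (0.24 and 0.24), of EGFR between genotypes with dimerizer (-0.0527 and -0.0533) and of KCNJ6 in the TGF-β1 interaction (0.43 and 0.89), and called MAPK8 between genotypes with dimerizer (-0.45 and -0.51). TPM divides by gene length and by the total over genes, and the cause of these changes was not tested. The camera adjusted p (limma) of the TGF-β response, mesenchymal and protease lists, WT TGF-β1 against control, ran from 0.00741 to 0.0744 with 1 library left out. Over the 11 comparisons of 26 lists camera with an estimated correlation passed 14 and with the replicate block 14, while the preset correlation passed 112 of 286, and fry, which does not set members against other genes, passed 232.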

Other observations

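The tests in this part were chosen only after the results of the report had been seen, apart from the lists, which had been fixed. Markers of cell types that a pure epithelial culture should lack were counted. Of 10 measured fibroblast markers 3 rose and 2 fell in WT dimerizer, with DCN, a proteoglycan of connective tissue, at -0.84 ± 0.13 and FBLN1 at -1.72 ± 0.10, 5 rose and 1 fell with TGF-β1 in WT (7 and 1 against control), and 8 rose and 0 fell with TGF-β1 in JNKKO, with DPT at 5.24 ± 0.33 and FBLN1 at 1.53 ± 0.10 (camera of limma, adjusted p = 0.988, 0.337 (0.249) and 0.0637 with an estimated correlation). Immune and endothelial markers 5 rose and 3 fell of 11 in WT dimerizer, with the integrin ITGAM at 2.17 ± 0.26 and CD14 at -1.33 ± 0.17 (camera of limma, adjusted p = 0.988 with an estimated correlation). The endothelial adhesion gene PECAM1 rose by 1.20 ± 0.14 there, while KDR, a receptor of the same cells, was at -0.87 ± 0.06. Mammary epithelial cells in culture can express several of these genes themselves.

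Notch pathway genes in WT dimerizer (5 rose and 3 fell of 16 (4 and 3 adjusted over the list alone)) included the ligand DLL1 at 1.62 ± 0.26 and the target HES1 at 0.50 ± 0.08, and in JNKKO dimerizer DLL1 was at -1.91 ± 0.21 and NOTCH1 at -0.82 ± 0.06. Heat shock genes in WT dimerizer 5 rose and 6 fell of 14 (5 and 7 adjusted over the list alone) (6 and 4 on log2(TPM + 1), where the majority turns), with the constitutive chaperone HSPA8 at 1.06 ± 0.04 and the small chaperone CRYAB at -2.54 ± 0.10. The adjusted p were 0.988 and 0.974 for these lists by camera of limma with an estimated correlation.

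The dimerizer response of JNKKO cells was set beside the TGF-β1 response of WT cells, a pair of comparisons with no library in common. At 1897 genes both were higher (1269 for independent lists), at 1405 both were lower (963) and at 1956 they were opposite. The opposite count joins genes higher in the first and lower in the second with those the other way round. It is therefore not comparable with either shared count alone. No value for independent lists was computed for it, so whether it is a deficit or an excess is not given here. Across the 16911 genes, which are not independent replicates, the Pearson r was 0.281 and the Spearman rho 0.212.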
